A study of Mus musculus with 6 samples.

How the data were processed

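The series holds 6 arrays hybridized with total RNA of explanted neonatal mouse cardiomyocytes, 3 from cells infected with a green fluorescent protein adenovirus (control) and 3 from cells infected with a Cre adenovirus (SRF-null). Groups and replicate numbers were taken from the sample titles. The deposited table gives 1 value per probe set and array for 45037 probe sets and 64 controls with Affymetrix mouse names. The deposited values are intensity values on a linear scale, which follows from their range, with maxima between 5913 and 10114 and minima below 0. The software, background or mismatch subtraction and scaling that the authors used to make these intensities are not given in the sources used here. Part of the values lay below 0 and array medians lay between 68.9 and 75.6, and any centring or target level behind them stays unknown. The labels name Cy3 as the dye, and nothing in the sources used here explains how that dye was used on these arrays. No detection calls or scanner files were used here. All 6 columns of the table were mapped to samples by title, and 0 columns were left over.

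Values below 0 were set to 0, and log2(intensity + 13.4) was taken, where 13.4 is the 10th percentile of all positive values over the 6 arrays. A fold change on this scale understates the change of dim genes. Because array medians on this scale spanned 0.113, above the limit of 0.1, the arrays were quantile-normalized with limma, after which 64 control probe sets were left out. The 30% of the remaining 45037 probe sets with the lowest mean over all 6 arrays were left out, which kept 31526. Gene names came from the platform annotation of the probe sets, in which 34945 probe sets had 1 gene symbol, 932 had several and 9160 were not listed. Of the first kind, 34741 were matched by gene ID to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols, and the rest kept the annotation's name. Probe sets with several symbols or none were not used for genes. Each gene was represented by its kept probe set with the highest mean over all 6 arrays, which gave 15267 genes. Of the 82 genes named by the rule below, 43 had other kept probe sets, and for 18 of these at least 1 went the other way. No genome coordinates are given, since the table names no genome build.

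Groups were compared with lmFit and eBayes of limma 3.58.1 (mean-variance trend on, no covariates, 4 residual degrees of freedom before moderation) in R 4.3.3. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. A second count also required a fold change of at least 1.5. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. The number of arrays limits the precision of every value.

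A set of 22 gene lists was tested with camera at its preset correlation of 0.01, adjusted over the lists. They were SRF-dependent actin and contractile cytoskeleton, immediate early genes, sarcomere thin filament, sarcomere thick filament with Z-disc and M-line, costamere and intercalated disc, calcium handling and ion channels, hypertrophy and fetal gene program, cardiac transcription factors and SRF cofactors, fatty acid oxidation, TCA cycle and oxidative phosphorylation, glycolysis, cell proliferation, p53 and DNA damage response, interferon response, unfolded protein and integrated stress response, heat shock proteins, and markers of fibroblasts, smooth muscle and pericytes, endothelium, leukocytes and macrophages, epicardium and mesothelium, and erythroid cells. The erythroid list had 1 measured member, below the minimum of 5, so 21 lists were tested. Genes were named by a fixed rule: Srf, then up to 10 genes per direction with the largest change among those called and not overlapping between groups, clone and predicted names left out, then up to 4 members of each list with the smallest p. This rule named 82 genes, and any other gene in the text was chosen after its values had been seen. The groups, design, tests, lists, naming rule and most alternatives were chosen before the data were examined.

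The replicate numbers come from the sample titles, which do not say what they stand for. Deviations from the group mean, across genes, correlated at 0.504, 0.465 and 0.304 between the control and SRF-null arrays numbered 1, 2 and 3, all above the limit of 0.1 set for pairing. The numbers were therefore taken to pair the samples, and values with the number as a block (2 residual degrees of freedom before moderation) are given where they change a call or move a count by over 1.5 times. Deviations within a group cancel out, so the strongly deviating replicate 1 arrays push arrays 2 and 3 of both groups the other way. Arrays 2 and 3 correlated above 0.1 between groups in every combination, down to 0.132 for control 2 with SRF-null 3. The check could therefore hardly fail for pairs 2 and 3, which limits every result with the block. Control replicate 3 correlated more with SRF-null replicate 2 (0.383) than with its own partner, so the pairing beyond replicate 1 is not shown.

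Other settings were no normalization between arrays, median centring, no filter on dim probe sets, a filter at 50%, the mean of all probe sets of a gene, all probe sets as separate features, no variance trend, array weights, a smaller and a larger pseudocount, each array left out in turn, camera with an estimated correlation, and fry. Leaving out both replicate 1 arrays, treating them as a batch in the model, and combining the block with an estimated correlation were added after the data had been seen. In fits with fewer arrays the filter and each gene's brightest probe set were chosen anew, so a gene's probe set can change. The fit was tested on simulated data with the spread of these arrays, 15267 genes and 200 changed genes. It called 8 of 67 genes changed 2-fold (11.9%), 46 of 67 changed 4-fold (68.7%) and 58 of 66 changed 8-fold (87.9%), with 1 false call, and made 0 calls in unchanged data. The simulated arrays varied independently, whereas same-numbered real arrays shared deviations, so the shares recovered may differ in the real data. A simulated shift of -0.5 in a list of 24 genes was called by camera in 20 of 20 data sets and with an estimated correlation in 17, with 2 false calls in 360 tests of unshifted lists. The simulated genes varied independently of each other, whereas the estimated correlation reached 0.74 for a list in the real data. These counts therefore do not show how often camera at its preset correlation makes false calls on correlated lists.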

Results

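Gene expression was measured on 6 single-channel oligonucleotide arrays, 1 per RNA sample, from cultured heart muscle cells of newborn mice. In 3 control samples the cells had been infected with an adenovirus carrying green fluorescent protein. In 3 SRF-null samples an adenovirus carrying Cre recombinase had been used to excise the floxed gene of serum response factor (SRF), a transcription factor that binds CArG boxes in the promoters of muscle and growth-response genes. The comparison of the 2 groups asks which transcripts differ when SRF is removed from cardiomyocytes. Each array gave values for 45037 probe sets besides controls, with median intensities of 74.3, 69.8 and 70.4 on the control arrays and 75.6, 71.4 and 68.9 on the SRF-null arrays. Unless stated otherwise, levels are the mean intensity ± SD (n = 3 arrays per group), changes are SRF-null over control on the log2 scale ± SE, and adjusted p-values come from limma. Nothing in the labels says that the samples came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

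Srf itself was measured by a pair of probe sets. On the brighter one the control intensities were 384, 439 and 467 (430.0 ± 42.4) and the SRF-null intensities were -2.28, 81.0 and 80.1 (52.9 ± 47.8), so every SRF-null array lay below every control array. The log2 change was -3.13 ± 0.71, with an adjusted p of 0.999 over 15267 genes. On the other probe set control arrays read 70.2, 169 and 177 and SRF-null arrays read 7.62, 128 and 138, a log2 change of -0.85 ± 0.74. Where either probe set lies relative to the excised part of Srf is not given in the sources used here, and a probe set outside that part need not show the excision. The Srf value of SRF-null replicate 1 lay below 0 and was set to 0 before the log2 step, so its distance from the other arrays has no exact size. Without both replicate 1 arrays the log2 change was -2.33, with an adjusted p of 0.0378, where the alternatives ranged from 0.0378 to 1.00 and the replicate block gave 0.266.

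The replicate 1 arrays of both groups stood apart from the other 4 arrays. BioB, a bacterial transcript spiked into every hybridization, read 2142 in control replicate 1 and 2177 in SRF-null replicate 1, against 186 to 269 elsewhere. The ratio of the 5′ to the 3′ beta-actin probe set, a sign of RNA length, was 0.391 and 0.430 in the replicate 1 arrays and 0.658 to 0.740 in the others. Values at or below 0 made up 9.43% and 8.45% of the probe sets on the replicate 1 arrays and 3.06% to 3.89% on the others. Across genes, which are not independent replicates, normalized log2 values correlated at 0.924 to 0.969 among the other 4 arrays. The replicate 1 arrays correlated at 0.758 to 0.825 with those 4 and at 0.828 with each other. Each group held 1 such array, so this split does not follow the comparison.

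**Figure D1:**
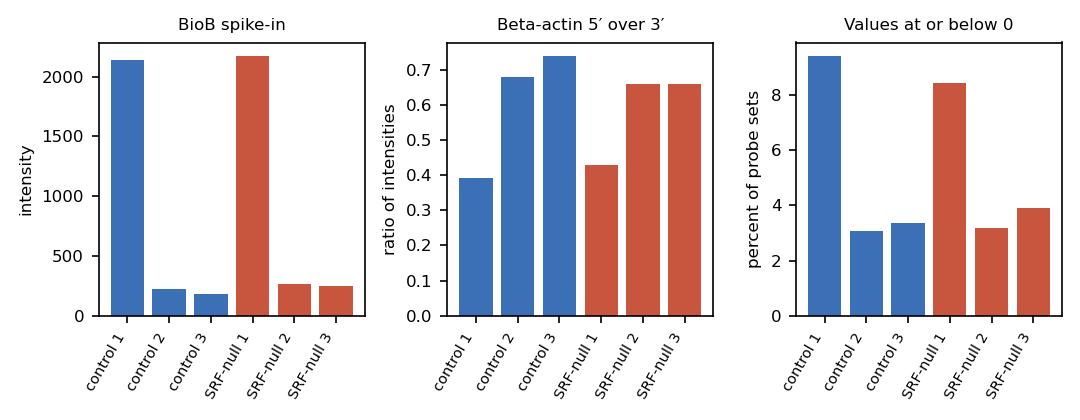
BioB spike-in intensity, the beta-actin 5′ over 3′ intensity ratio and the percentage of values at or below 0, as 1 bar per array for 3 control (blue) and 3 SRF-null (red) arrays. In every panel the 2 replicate 1 arrays differ from the other 4, with BioB at 2142 and 2177 against at most 269.

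Troponin C of slow and cardiac muscle, Tnnc1, was the 1 gene that passed the threshold across all genes. Its intensity fell from 3844 ± 577 in control to 610.2 ± 78.6 in SRF-null cells, 6.16-fold on the log2 scale used, a log2 change of -2.62 ± 0.15 (adjusted p = 0.00653). Skeletal alpha-actin, Acta1, measured 644 ± 216 in control and 43.2 ± 11.7 in SRF-null arrays, with a log2 change of -3.52 ± 0.32 that missed the threshold (adjusted p = 0.0773). The muscle ankyrin-repeat protein gene Asb2 (log2 change -2.55 ± 0.27) and muscle creatine kinase, Ckm (-2.46 ± 0.26), both had an adjusted p of 0.0919, although the dimmer Ckm probe set, at 53.3 in control arrays, gave -0.04. The olfactory receptor gene Olfr544 (-2.65 ± 0.28) had the same adjusted p. B-type natriuretic peptide, Nppb, measured 3178 ± 1510 against 808 ± 614, with a log2 change of -2.10 ± 0.49. All of these genes were lower in each SRF-null array than in any control array. Asb2, Ckm and Olfr544 were named after their values had been seen.

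Of 15267 genes tested with limma, 1 was lower and 0 were higher at an adjusted p under 0.05, and the 1 call also exceeded the fold minimum of 1.5. At an unadjusted limma p under 0.05 chance alone gives a share of 0.05 of the 15267 genes. The main fit gave fewer than that, 391 in all, and the replicate block gave more, 1038 in all. Of these, 235 were lower and 156 higher in the main fit, and 588 lower and 450 higher with the block. This balance turned to more higher than lower genes with array weights (751 against 554), without control replicate 1 (422 against 243), without control replicate 3 (185 against 130) and without both replicate 1 arrays (424 against 406), while leaving out SRF-null replicate 1 gave 163 lower and 73 higher. All 3 SRF-null arrays lay below all 3 control arrays for 5.09% of genes and above them for 4.03%, where chance gives 10% for both directions together. For a single gene, 3 against 3 arrays cannot give an exact two-sided permutation p below 0.1. With the replicate number as a block, 5 genes were called, all lower, namely Tnnc1 (adjusted p = 0.00374), Acta1 (adjusted p = 0.0205), Asb2 and Ckm (both with adjusted p = 0.0231) and Nppb (adjusted p = 0.0487). Without both replicate 1 arrays, 3 genes were called, Tnnc1, Srf and Hacd1, and with those arrays as a batch in the model the count was 1, while a replicate 1 pair of 1 against 1 allows no test of its own. Tnnc1 kept its call without control replicate 1, but its adjusted p was 0.0864 to 0.133 when any of the other 5 arrays was left out. Its log2 change in those fits was -2.55 to -2.67. The adjusted p of Tnnc1 was 0.0586 when arrays were centred on their medians in place of quantile normalization. Over alternatives the adjusted p ranged from 0.000123 to 0.133 for Tnnc1 and from 0.0189 to 0.398 for Acta1.

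**Figure D2:**
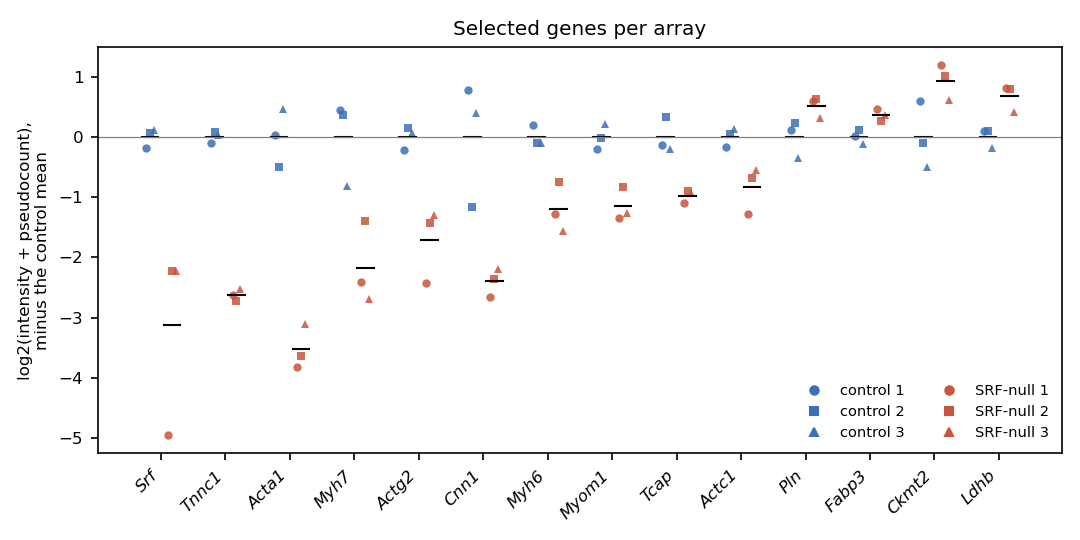
Log2(intensity + pseudocount) of 14 genes on each array after normalization, minus the mean of the 3 control arrays, with control arrays in blue, SRF-null arrays in red, a marker shape per replicate number and a black bar for each group mean. Tnnc1 lies at -2.62 from the control mean with little spread between arrays, while Srf spreads widely because SRF-null replicate 1 read below 0.

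Genes of the actin and contractile cytoskeleton that are known SRF targets were mostly lower in SRF-null cells. Of 30 members, 28 had a negative log2 change, with a mean of -0.70 and a median of -0.46. Besides Acta1, enteric smooth muscle actin, Actg2, measured 498 ± 56.5 in control and 153 ± 60.7 in SRF-null arrays (log2 change -1.72 ± 0.32). With array weights, Actg2 (adjusted p = 0.0344, range over alternatives 0.0344 to 1.00) and Acta1 (adjusted p = 0.0189, range 0.0189 to 0.398) passed across all genes. In that fit control replicate 2 had a weight of 4.95 and the other arrays 0.18 to 1.75, so 1 array counted most on the control side. Calponin, Cnn1, had a log2 change of -2.40 ± 0.50, cardiac alpha-actin, Actc1, of -0.83 ± 0.22, and the regulatory light chain Myl9 of -1.46 ± 0.44. Several abundant members showed no such difference, among them the cytoplasmic actins Actb (0.15 ± 0.36) and Actg1 (0.00 ± 0.21) and vinculin, Vcl (-0.04 ± 0.17). The list fell by camera (adjusted p = 1.57e-16), although its adjusted p = 0.147 with an estimated correlation (range over alternatives 1.26e-19 to 0.195). Adjusted over the list alone, 11 members fell and none rose, against 0 members called over all genes tested, and with the replicate block 17 fell. Pdlim7 was among the 11 on its brightest probe set (-2.04 ± 0.34), whereas its 2 other probe sets gave -0.83 and -0.09. On the brightest one every SRF-null array lay below every control array, and the pairs gave -2.01, -1.71 and -2.41. The fits without control replicate 1 (-0.16) or control replicate 3 (-0.0566) chose the probe set anew. Those values come from another probe set and do not show how far a single array moves the change.

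Thick filament, Z-disc and M-line genes were also lower as a group. Of 24 members, 22 had a negative log2 change, with a mean of -0.56 and a median of -0.46. The beta-myosin heavy chain, Myh7, measured 2389 ± 966 in control and 535 ± 247 in SRF-null arrays (log2 change -2.17 ± 0.45), and the alpha heavy chain, Myh6, 5243 ± 162 and 2407 ± 656 (-1.20 ± 0.23). The M-band protein gene Myom1 had a log2 change of -1.14 ± 0.20, the titin cap gene Tcap of -0.98 ± 0.21 and the atrial light chain Myl4 of -0.86 ± 0.22. Cardiac myosin-binding protein C, Mybpc3, was the member farthest in the other direction, at 0.37 ± 0.14. The list fell by camera (adjusted p = 2.35e-13) and was the only list whose call held with an estimated correlation (adjusted p = 0.0223). Adjusted over the list alone, 5 members fell, against 0 called over all genes tested, and with the replicate block 15 fell and 1 rose. With the block and an estimated correlation together the adjusted p was 0.267, the highest of its alternatives, which began at 2.60e-16.

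Thin filament genes lay on both sides of 0. Tnnc1 and Acta1 had the largest changes of the list, and Actc1 and the actin-binding repeat protein gene Xirp1 (-0.75 ± 0.22) were lower as well. The slow skeletal troponin I gene Tnni1, expressed in the fetal heart, had a log2 change of 0.64 ± 0.23, while cardiac troponin T, Tnnt2, and cardiac troponin I, Tnni3, gave 0.09 ± 0.15 and 0.24 ± 0.26. Of 14 members 7 were lower and 7 higher, so the mean was -0.48 and the median 0.03, of opposite sign, and camera's direction was that of the mean. Camera called the list lower (adjusted p = 0.00571; adjusted p = 0.142 with an estimated correlation). The call was lost without control replicate 1 (adjusted p = 0.127) and without both replicate 1 arrays (adjusted p = 0.0643) or with array weights (adjusted p = 0.0548), within a range of 0.00189 to 0.312 over alternatives. Adjusted over the list alone, 4 members fell, against 1 over all genes tested, and the replicate block gave 6 lower and 2 higher.

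Genes of the hypertrophic and fetal program had the most negative mean of the tested lists, -0.97 over 11 members, with 10 lower and a median of -0.76. Acta1, Myh7 and Nppb led it. The calcineurin regulator Rcan1 had a log2 change of -1.12 ± 0.56 and atrial natriuretic peptide, Nppa, of -0.24 ± 0.18. Tnni1 was the member that was higher. The list fell by camera (adjusted p = 3.29e-09; adjusted p = 0.142 with an estimated correlation; range over alternatives 1.51e-11 to 0.267). Adjusted over the list alone, 6 members fell and 1 rose, against 0 over all genes tested. The list shared 6 of its 11 members with the contractile lists.

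**Figure D3:**
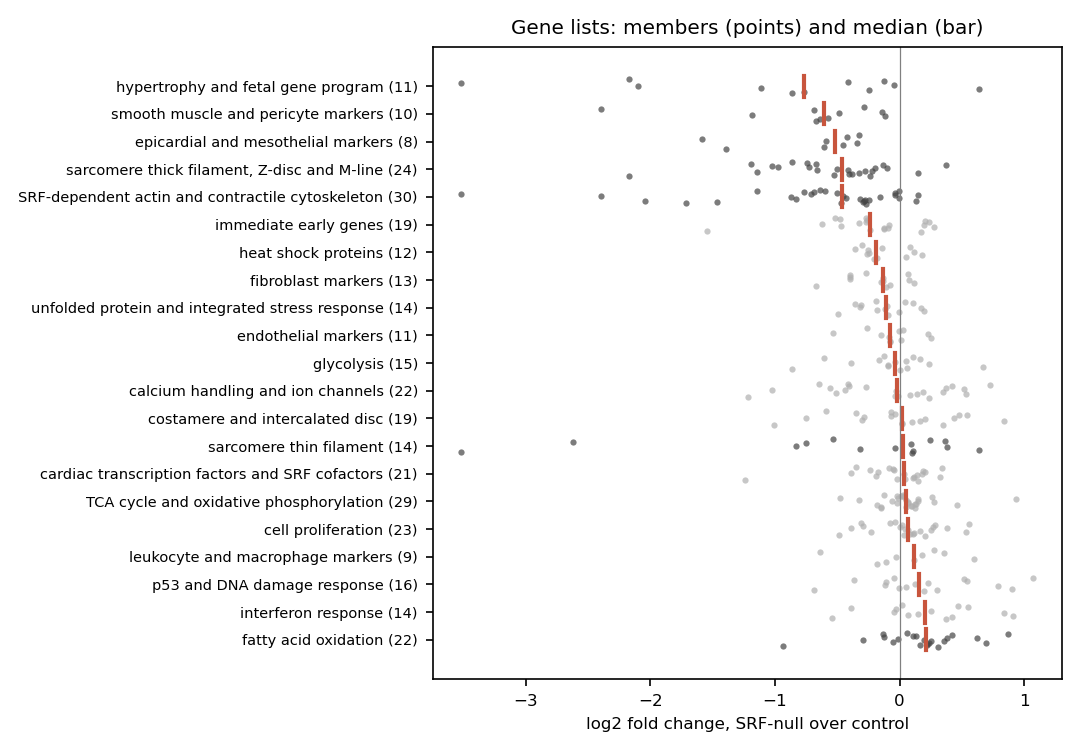
Log2 change, SRF-null over control, of every tested member (points) of the 21 tested gene lists, with the list median as a red bar, the number of members in parentheses and dark points for lists called by camera. The contractile, hypertrophic, smooth muscle and epicardial lists lie mostly below 0, with medians from -0.76 to -0.46, and the thin filament list, also called, has a median of 0.03.

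Genes of calcium handling and ion channels split in both directions, 12 lower and 10 higher of 22. Junctophilin, Jph2, which tethers the sarcoplasmic reticulum to the T-tubule, measured 1115 ± 250 in control and 540 ± 33.2 in SRF-null arrays, a log2 change of -1.02 ± 0.19. Its other, dimmer probe set gave 0.24, and the mean of both gave -0.39. Calsequestrin, Casq2, gave -0.56 ± 0.18 and the potassium channel subunit Kcne1 gave -1.22 ± 0.64. Kcne1 was at -0.70 without control replicate 2 and at -0.64 without SRF-null replicate 1. Phospholamban, Pln, which inhibits the calcium pump, measured 2762 ± 561 against 3943 ± 303 (0.52 ± 0.20). The list was not called (adjusted p = 0.196 by camera, mean -0.09), and adjusted over the list alone 1 member, Jph2, fell, against 0 over all genes tested. With the replicate block 4 members fell and 1 rose on the list-alone adjustment. The list mean was -0.03 without control replicate 1 and -0.18 without control replicate 3.

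Costamere and intercalated disc genes were divided, 9 lower and 10 higher of 19. Plakophilin 2, Pkp2, measured 1212 ± 208 in control and 716 ± 17.3 in SRF-null arrays (-0.75 ± 0.18), while its desmosomal partner desmoplakin, Dsp, measured 1285 ± 165 and 1892 ± 124 (0.54 ± 0.16). Dystrophin, Dmd, gave -0.59 ± 0.21 and beta-sarcoglycan, Sgcb, -1.01 ± 0.44 (-0.50 without SRF-null replicate 1). The list was not called (adjusted p = 0.959, mean -0.02, median 0.02), and 0 members passed either when adjusted over the list alone or over all genes tested. The replicate block gave 2 lower and 2 higher on the list-alone adjustment.

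Fatty acid oxidation genes were higher in SRF-null cells as a list, 16 of 22, with a mean of 0.17 and a median of 0.21. The heart fatty acid-binding protein Fabp3 measured 1846 ± 147 in control and 2401 ± 229 in SRF-null arrays (0.36 ± 0.15). The fatty acid transporter Cd36 gave 0.69 ± 0.31 and the coactivator Ppargc1a 0.87 ± 0.40 (0.13 to 0.39 on its other probe sets). Pyruvate dehydrogenase kinase 4, Pdk4, went the other way (-0.94 ± 0.30). The list rose by camera (adjusted p = 0.0296; adjusted p = 0.555 with an estimated correlation), and 0 members passed when adjusted over the list alone or over all genes tested. The call was lost without control replicate 3 (adjusted p = 0.293) and without SRF-null replicate 2 (adjusted p = 0.456), and with array weights (adjusted p = 0.160) or no variance trend (adjusted p = 0.0536), within a range of 0.00341 to 0.623. The mean was 0.0767 without SRF-null replicate 2 and 0.0743 with array weights, and the replicate block gave 1 lower and 1 higher member on the list-alone adjustment.

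Other energy genes lay nearer 0 as groups. Among 29 genes of the TCA cycle and oxidative phosphorylation, sarcomeric mitochondrial creatine kinase, Ckmt2, measured 866 ± 365 against 1617 ± 326 (0.93 ± 0.31), fumarase, Fh1, gave -0.48 ± 0.22, Ogdh 0.46 ± 0.25 and Dlat -0.32 ± 0.23. In glycolysis, lactate dehydrogenase B, Ldhb, measured 974 ± 121 against 1582 ± 218 (0.67 ± 0.18), the glucose transporter Slc2a1 gave -0.86 ± 0.52, hexokinase 2, Hk2, -0.60 ± 0.40 and Pfkm 0.24 ± 0.19. Neither list was called (adjusted p = 0.531 and 0.994), and 0 members of either passed when adjusted over the list alone or over all genes tested. The glycolysis list had a mean of -0.07 and a median of -0.04, while camera placed it upward. The TCA list was called higher without SRF-null replicate 3 (adjusted p = 0.0126, range over alternatives 0.0126 to 0.996; adjusted p = 0.957 with an estimated correlation and all arrays). With the replicate block, Ckmt2 and Ldhb were higher and Slc2a1 was lower on the list-alone adjustment.

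Immediate early genes, which include textbook SRF targets, had 14 lower and 5 higher of 19 members, with a mean of -0.23 and a median of -0.24. The mean was -0.13 without control replicate 3. Egr1 measured 471 ± 210.1 in control and 183 ± 129 in SRF-null arrays (-1.54 ± 0.60, and -0.89 without SRF-null replicate 1), the phosphatase Dusp1 gave -0.47 ± 0.23 and Maff -0.51 ± 0.27, and Mcl1 gave 0.28 ± 0.16. Fos itself was at -0.09 ± 0.40. The list missed the threshold (adjusted p = 0.0580), and 0 members passed when adjusted over the list alone or over all genes tested. It was called lower with the replicate block (adjusted p = 0.0141, 1 member on the list-alone adjustment, Egr1), although the adjusted p = 0.278 with the block and an estimated correlation and 0.555 with an estimated correlation alone. It was also called without control replicate 1 (adjusted p = 0.0386), control replicate 2 (adjusted p = 0.0381) or SRF-null replicate 3 (adjusted p = 0.00956), and with the replicate 1 arrays as a batch (adjusted p = 0.0438), with the lowest 50% of probe sets left out (adjusted p = 0.0278), with the mean of all probe sets (adjusted p = 0.0299) or with 4 times the pseudocount (adjusted p = 0.0474), within a range of 0.00956 to 0.623. Without both replicate 1 arrays the adjusted p was 0.0527.

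Cardiac transcription factors and SRF cofactors lay on both sides of 0, 10 lower and 11 higher of 21. The ternary complex factors Elk1 and Elk4 gave -1.24 ± 1.38 and -0.39 ± 0.20, Tbx5 0.34 ± 0.24, Mef2a 0.32 ± 0.28 and Hand2 0.20 ± 0.19, while Gata4 gave 0.11 ± 0.30 and Nkx2-5 0.14 ± 0.24. The other Elk4 probe sets gave 0.20, 0.20 and 0.00, and those of Mef2a -0.84 to 0.17. The list was not called (adjusted p = 0.994), its mean was -0.05 and its median 0.03, camera pointed up, and 0 members passed when adjusted over the list alone or over all genes tested.

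Markers of other cell types that a heart culture can hold differed between lists. All 10 smooth muscle and pericyte markers were lower (mean -0.72, median -0.61), led by Cnn1, Des (-0.67 ± 0.24), Cspg4 (-0.58 ± 0.23) and Acta2 (-0.64 ± 0.27), and 4 of the 10 are also in the contractile lists. All 8 epicardial and mesothelial markers were lower (mean -0.71, median -0.52), with Krt18 at 502 ± 252 against 176 ± 77.4 (-1.39 ± 0.44), Krt19 at -1.58 ± 0.99, Aldh1a2 at -0.42 ± 0.31 and Wt1 at -0.59 ± 0.58. With single arrays left out, Krt19 ranged from -2.52 to -1.01. Wt1 was at -0.03 without control replicate 3 and -0.98 without control replicate 1. Aldh1a2 was at -0.13 without SRF-null replicate 1 and -0.67 without SRF-null replicate 3. Camera called both lists lower, at an adjusted p of 4.45e-07 for smooth muscle (adjusted p = 0.142 with an estimated correlation) and 0.00971 for epicardium (adjusted p = 0.556 with an estimated correlation). The epicardial call was lost without control replicate 3 (adjusted p = 0.540), SRF-null replicate 1 (adjusted p = 0.0998) or SRF-null replicate 2 (adjusted p = 0.307), and without both replicate 1 arrays (adjusted p = 0.102) or with array weights (adjusted p = 0.605). The epicardial mean of -0.71 was -0.13 without control replicate 3, -0.42 without SRF-null replicate 1, -0.44 without SRF-null replicate 2, -1.08 without control replicate 2, -1.27 without SRF-null replicate 3 and -0.18 with array weights. The smooth muscle median of -0.61 was -0.32 without both replicate 1 arrays, and -0.82, -0.55 and -0.17 in pairs 1, 2 and 3. On second probe sets Des gave -0.05 and Cspg4 0.09. Over alternatives the adjusted p ranged from 2.38e-07 to 0.278 for the smooth muscle list and from 6.30e-06 to 0.733 for the epicardial list. Adjusted over the list alone, 1 smooth muscle marker, Cnn1, fell (3 with the replicate block) and 0 epicardial markers did (2 with the block), against 0 of either over all genes tested.

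The remaining cell type lists were not called. Fibroblast markers had 10 of 13 lower (mean -0.19, adjusted p = 0.0956), including Mfap5 (-0.67 ± 0.21), Col5a1 (-0.40 ± 0.20), Ddr2 (-0.27 ± 0.23) and Postn (-0.15 ± 0.23), while other probe sets gave 0.14 and -0.16 for Col5a1 and 0.24 for Ddr2. That list was called lower with the replicate block (adjusted p = 0.0174) and without control replicate 1 (adjusted p = 0.00358), SRF-null replicate 2 (adjusted p = 0.0156) or SRF-null replicate 3 (adjusted p = 0.0200). With an estimated correlation the adjusted p was 0.809, or 0.389 with the block added, and the fibroblast mean turned to 0.26 without SRF-null replicate 1. With the replicate 1 arrays as a batch the adjusted p was 0.0173, without both of them it was 0.190, and the range over alternatives was 0.00358 to 0.898. Endothelial markers had 7 of 11 lower (mean -0.06, adjusted p = 0.787), with Tek at -0.54 ± 0.38, Eng at 0.23 ± 0.24, Flt1 at -0.26 ± 0.38 and Cldn5 at 0.25 ± 0.40. Leukocyte and macrophage markers had 4 of 9 lower (mean 0.06, adjusted p = 0.787), with C1qc at -0.64 ± 0.44, Csf1r at 0.60 ± 0.54, Cd14 at 0.28 ± 0.24 and Tyrobp at -0.18 ± 0.24. In these lists 0 members passed when adjusted over the list alone or over all genes tested. Of the erythroid markers 1 was measured, Slc4a1 (0.16 ± 0.18), too few for a list test.

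Among growth and stress lists, p53 and DNA damage genes were higher in 10 of 16 cases (mean 0.21, adjusted p = 0.0815), with Bbc3 at 0.90 ± 0.41, Ccng1 at 0.54 ± 0.28, Fas at 1.07 ± 0.65 and Cdkn1a at 1196 ± 33.4 against 1430 ± 117 (0.23 ± 0.14). Without control replicate 1, Fas was at 0.30 and Bbc3 at 0.43, while Ccng1 was at 0.82 without it and at 0.35 without SRF-null replicate 1. That list was called higher with the replicate block (adjusted p = 0.0199, 1 member on the list-alone adjustment, Ccng1) and without both replicate 1 arrays (adjusted p = 0.0496) or with them as a batch (adjusted p = 0.0449), and with the lowest 50% of probe sets left out (adjusted p = 0.0189), within a range of 0.0189 to 0.623. With an estimated correlation its adjusted p was 0.537, or 0.278 with the block added. The p53 mean of 0.21 was 0.13 without both replicate 1 arrays, 0.0665 without control replicate 1 and 0.0884 without SRF-null replicate 2. Interferon response genes were higher in 10 of 14 cases (mean 0.22, adjusted p = 0.0613), with Ifit3 at 0.55 ± 0.20, Iigp1 at 0.84 ± 0.35, Irf7 at 0.37 ± 0.23 and Gbp2 at -0.54 ± 0.31. The interferon list was called higher without both replicate 1 arrays (adjusted p = 0.00409), without control replicate 2 (adjusted p = 0.0245) and without SRF-null replicate 1 (adjusted p = 0.00384) and with 4 times the pseudocount (adjusted p = 0.0474), within a range of 0.00384 to 0.696. The mean was 0.0879 without control replicate 1 and 0.34 without SRF-null replicate 1, and its adjusted p = 0.556 with an estimated correlation. Cell proliferation genes were higher in 16 of 23 cases (mean 0.06, adjusted p = 0.523), with Bub1b at 0.56 ± 0.32, Aurka at 0.54 ± 0.34, Mcm3 at -0.29 ± 0.21 and Mcm4 at -0.31 ± 0.23. In these lists too, 0 members passed when adjusted over the list alone or over all genes tested.

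The unfolded protein and integrated stress response list had 10 of 14 lower (mean -0.12, adjusted p = 0.196), with Sel1l at -0.49 ± 0.25, Atf4 at -0.36 ± 0.25, Atf3 at -0.31 ± 0.24 and Calr at 0.20 ± 0.16. The other Atf4 probe sets gave -0.01 and 0.00, and those of Sel1l 0.04, -0.08 and 0.18. It was called lower without control replicate 1 (adjusted p = 0.0469) or SRF-null replicate 3 (adjusted p = 0.0403), within a range of 0.0403 to 0.814. The mean was -0.23 and -0.21 in these cases, -0.0148 without control replicate 3 and -0.00420 without SRF-null replicate 1, and its adjusted p = 0.698 with an estimated correlation. Heat shock protein genes had 8 of 12 lower (mean -0.13, adjusted p = 0.396), with Hspb6 at -0.35 ± 0.24, Hsp90aa1 at 0.18 ± 0.15, Dnajb1 at -0.20 ± 0.22 and Hspb7 at -0.30 ± 0.36. The heat shock mean was -0.02 without control replicate 1 and -0.04 without SRF-null replicate 2. It was -0.21 without control replicate 2 and -0.22 without SRF-null replicate 1. Adjusted over the list alone, 0 members of either list passed, as over all genes tested.

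Camera called 7 of the 21 tested lists, 6 lower and 1 higher, and 10 with the replicate block, which added the immediate early, p53 and fibroblast lists. The count was 11 without SRF-null replicate 3 and 5 without control replicate 3. With an estimated correlation the thick filament, Z-disc and M-line list alone was called, and 0 lists were called when the block was added to that. Estimating the correlation also lowers the degrees of freedom of the list test to the residual ones, 4, or 2 with the block. A call lost there therefore need not reflect correlation. The thin filament list lost its call (camera adjusted p = 0.142) at an estimated correlation of -0.07, below the preset 0.01. Fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, called the thin filament (adjusted p = 0.00201) and thick filament lists (adjusted p = 0.00836). Its test of change in either direction called the SRF-dependent actin (adjusted p = 0.00378), thin filament (adjusted p = 0.000334), thick filament (adjusted p = 0.00180) and hypertrophic lists (adjusted p = 0.00243).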

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

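The test of the normalization and the counts of other splits of the arrays were chosen before their results were seen, and every other test in this part was chosen after the result was seen.

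A control probe set of the spike-in gene Phe, AFFX-PheX-5_at, read higher in all SRF-null arrays than in all control arrays, with a mean intensity of 36.4 against 12.5. It was 1 of 64 control probe sets with such an order, where chance gives 3.2.

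Contractile genes were lower in the SRF-null arrays, with a median log2 change of -0.42 over the 65 members of the thin filament, thick filament and SRF-dependent actin lists. A smaller share of cardiomyocytes would lower other cardiomyocyte genes about as far. A set of 17 such genes outside those lists, chosen after the values were seen, had a median of 0.14. That was above the contractile lists by 0.57 ± 0.06 (SD over 3 pairs). The set left out other heart muscle genes that were lower, such as Nppb and Jph2, or higher, such as Dsp. Its median depends on that choice and does not settle the share of cardiomyocytes. Single genes among the 17 ranged from -0.56 (Casq2) to 0.93 (Ckmt2), a spread that the SD over pairs leaves out. Of the 17, 16 also belong to other lists used here. The noise of the replicate 1 arrays and the normalization are argued against as the whole cause, since the median was -0.43 without both replicate 1 arrays and at most -0.43 without normalization or with median centring. Loss of smooth muscle or epicardial cells would not lower thick filament genes, whose median outside those marker lists was -0.42, but it stays open for the actin genes, as smooth muscle markers outside the contractile lists had a median of -0.38 (-0.66, -0.17 and -0.10 in the 3 pairs) and epicardial markers of -0.52 (-0.64, -0.60 and -0.82). Also open is the hypothesis that loss of SRF lowers these genes, against an untested effect of Cre or viral load, which Cre virus on cells without floxed Srf would test.

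The replicate 1 arrays of both groups stood apart from the other 4. Each group held 1 of them, and no biological explanation was tested. An exchange of labels between the replicate 1 arrays is argued against, since 825 genes with an unadjusted limma p under 0.05 in replicates 2 and 3 alone went the same way in pair 1 by a median of 0.34, and 70.5% of them had that direction. Most of that shift came from the 404 lower genes, with a pair 1 median of -0.57, against 0.12 for the higher ones. A difference in labelling or hybridization between array runs may account for it, since the lowest BioB of the replicate 1 arrays was 7.97 times the highest of the other 4, and BioB is added to the sample and does not come from the cells. The spike-ins did not all shift alike. BioC was higher too (3160 and 3671 against 473 to 672) and BioDn less so (4200 and 3744 against 2278 to 3111). The Cre spike-in was lower (5265 and 4281 against 6805 to 8408). The SRF-null cells had received a Cre virus, but the control arrays alone showed the same order (5265 against 7941 and 6805). A difference between runs is a hypothesis, which the scan dates of the arrays would test.

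Few genes passed the threshold across all genes. The spread added by the replicate 1 arrays may contribute, a hypothesis that a repeat hybridization would test, since the median residual SD with that pair kept was 2.26 times that without it, and leaving out that pair gave 3 called genes while leaving out another pair gave 0. Of the 10 splits of the 6 arrays into 3 and 3, 2 gave at least as many called genes as the real split, itself counted, with or without the fold minimum (real value 1, highest other 61), and 4 gave at least as many called lists (real value 7, highest other 11), and 10 splits are too few for a share under 0.05. The split with 61 genes set control replicate 1, SRF-null replicate 1 and SRF-null replicate 3 against the rest, which points to a structure of the samples apart from the groups. The other 3 splits that part all 3 pairs gave 0 genes each, also with the replicate block, where the real split gave 5, and they gave 3, 3 and 0 lists. So few splits cannot give a share under 0.05 either, and the pairing beyond replicate 1 is not shown.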

How the results depend on the processing

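Array weights, the replicate block and the other settings listed with the methods were chosen before the data were examined, while both settings on the replicate 1 arrays and the block with an estimated correlation were chosen after. A list's direction here is the sign of its mean log2 change, and the cause of the changes was not tested unless fewer arrays or probe sets explain it by construction.

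The count of called genes, 1, was 5 in the paired fit with the replicate block, 11 with array weights, 3 without both replicate 1 arrays, 0 with median centring and 0 to 1 when each array was left out. The same values held with the fold minimum of 1.5, and every other setting gave 1. The number of called lists, 7, was 10 with the replicate block, 4 with array weights, 1 with an estimated correlation, 2 with fry, 0 with the block and an estimated correlation, and 5 to 11 with single arrays left out. Srf was called in 1 setting, without both replicate 1 arrays, at -2.33. It was -2.23 to -3.60 with single arrays left out. The block called Acta1 and Nppb among the genes named by the rule and the immediate early, p53 and fibroblast lists, and changed no other call.

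Of 81 other named genes, 69 kept their direction and their side of the threshold in every setting that gave them a value (18 for most, 17 for Fas, C1qc and Wt1), and 8 changed sign at least once. Of 21 lists, 2 kept both in all 21 settings, and 8 changed the sign of their mean. In fits with 1 array left out, 46 of the 81 genes and the means of 16 of the 21 lists moved by over 1.5 times in at least 1 case. These counts include genes whose probe set changed at the same time, such as Pdlim7 and Elk4, so not every move is due to the array. Mef2a (-0.0497), Hand2 (-0.0388) and Flt1 (0.20) changed sign with the mean of all probe sets, Gbp2 (0.0269) without both replicate 1 arrays and Cldn5 (-0.0773) with array weights. The Gbp2 value also came with a change of probe set, since pairs 2 and 3 gave -0.19 and -0.29 on the one used with all arrays. With single arrays left out, the range was -0.55 to 0.0699 for Hspb7, -0.31 to 0.0366 for Postn, -0.64 to 0.0319 for Flt1 and -0.10 to 0.48 for Cldn5. For Elk4 it was -0.49 to 0.35, but the positive values came with a change of probe set. On the Elk4 probe set used with all arrays, every SRF-null array lay below every control array. With array weights the mean was -0.0238 for the TCA list, 0.0241 for glycolysis, 0.0457 for endothelial markers and -0.0730 for leukocyte markers. The leukocyte mean was also -0.13 without a filter and -0.00766 with the mean of all probe sets. The cardiac transcription factor mean was 0.0140 with the lowest 50% of probe sets left out and 0.0501 without both replicate 1 arrays. With single arrays left out, the means ranged from -0.0723 to 0.0329 for costamere genes, -0.10 to 0.14 for cardiac transcription factors, -0.0368 to 0.17 for the TCA list, -0.17 to 0.00898 for glycolysis, -0.0645 to 0.15 for proliferation, -0.56 to 0.26 for fibroblast markers, -0.24 to 0.11 for endothelial markers and -0.00506 to 0.18 for leukocyte markers. Signal over background limits dim genes, since 3.06% to 9.43% of the values on an array were at or below 0.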

Other observations

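The genes in this part were chosen after their values had been seen, and none of them passed the threshold across all genes with all 6 arrays, equal weights and no block. With other settings Ckm and Asb2 passed with the replicate block and array weights, Hacd1 without both replicate 1 arrays and with array weights, and Ercc5 with array weights. Array weights also called Olfr544, Ccl24, Mgat4d and Gm28729.

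Among genes outside the lists, a few known from striated muscle were looked up, without a test of whether such genes are more frequent here than elsewhere. Calsequestrin 1, Casq1, the calcium store protein of fast skeletal muscle, measured 884 ± 409 in control and 151 ± 41.2 in SRF-null arrays, a log2 change of -2.36 ± 0.41. Hacd1, a fatty acid elongation enzyme of muscle, measured 1945 ± 459 against 369 ± 156 (-2.48 ± 0.36), and its other probe set gave -1.89. Itgb1bp2, which encodes the integrin-binding muscle protein melusin, measured 333 ± 79.6 against 51.9 ± 35.8 (-2.57 ± 0.48). Popdc2 gave -0.94 ± 0.20, the focal adhesion gene Lims2 -1.19 ± 0.23 and the actin-binding supervillin gene Svil -0.89 ± 0.21 (-0.51 on its other probe set). Together with Ckm and Asb2, these genes were lower in all 3 SRF-null arrays than in all 3 control arrays, an order that chance gives, in either direction, for 10% of genes.

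Some genes with higher values were looked up in the same way. The leucine-rich repeat gene Lrrc2 measured 282 ± 56.2 in control and 713 ± 79.3 in SRF-null arrays (1.30 ± 0.22), and its other probe set gave 1.11. Cd24a, a surface glycoprotein gene, measured 812 ± 121 against 1662 ± 137 (1.01 ± 0.17; 0.98 and 0.80 on its other probe sets), and the junctional adhesion gene Jam2 152 ± 52.2 against 352 ± 50.6 (1.16 ± 0.27). The other Jam2 probe sets gave 1.09, 0.88 and, at a similar brightness, 0.04. The probe sets of some genes disagreed: Ercc5 gave -1.93 on 1 probe set and 0.15 on the other, and Bmf gave -1.64, -0.98 and -0.03 on 3.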
